A study of Mus musculus with 10 samples.

How the data were processed

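The series holds 10 polyA RNA libraries from ovaries of mice aged 6 weeks on a mixed C57BL/6 and 129 background. Per the labels, whole gonads were homogenised in Trizol and libraries were made with a stranded mRNA kit. Controls (n = 5) carried floxed alleles of the retinoic acid receptor genes Rara, Rarb and Rarg and no Cre. Rar mutants (n = 3) carried the same floxed alleles with Sf1-Cre, a Cre recombinase driven by the promoter of Nr5a1, which is active in somatic cells of the gonad. Dmrt1 het Rar mutants (n = 2) carried in addition 1 floxed allele of Dmrt1, a regulator of gonadal sex. The series' design text gives 5 replicates in each of 2 genotypes, which the labels meet only when both kinds of Cre-positive ovary are pooled, so that grouping was used beside the grouping by label.

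Per the submitters' processing notes, reads were handled with Trimmomatic 0.32, STAR 2.4.2a, SAMtools 1.0 and DESeq2 1.12.3 on GRCm38 (mm10). The counting tool and annotation release are not stated there. The deposited count table gives a raw count for each Ensembl gene and library, for 24306 genes, of which 89 were at 0 in all libraries. The deposited FPKM table gives FPKM values that the authors scaled by median-of-ratios size factors, as the ratio of count to FPKM showed. The authors' table of differential expression holds, per the file headers, a mean normalised count (a signal), a log2 fold change with its standard error, a Wald score (the log2 fold change over that error), a p-value and an adjusted p-value. That deposited table lists 185 genes. Its mean counts lay within 0.0348% of the mean over the 5 control and 3 Rar mutant libraries, so it compares those groups, with fold changes shrunken toward 0. Gene positions came from GENCODE M21 on the same build, which matched 24038 of the 24306 identifiers; 438 identifiers had no symbol.

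Total counts ran from 21064856 to 25920131 per library. A count of 0 allows up to 3 counts, or 0.116 to 0.142 CPM, and covers counting error only. The 10 most abundant genes took 7.28% to 9.05% of the counts of a library, and no pair of libraries of the same group was a duplicate.

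Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (TMM normalisation, filterByExpr, robust dispersion), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call. All Rar-deleted ovaries were compared with controls in a 2-group fit of 18954 genes. The Rar mutants and the Dmrt1 het Rar mutants were compared with controls and with each other in a 3-group fit of 20570 genes, in which the groups share the estimate of spread. All n are libraries, each error beside a mean CPM is an SD, and each error beside a log2 fold change is an SE. For edgeR this SE is approximate, being the size of the fold change divided by the square root of its F statistic. Genes were assigned to 24 lists, tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and adjustment over the lists. Each list test was repeated with an estimated correlation and with fry, whose test asks whether the genes of a list move on balance in 1 direction. Members of a list were also adjusted over the list alone. In simulated data of the same group sizes, the pooled comparison recovered 67.0% of genes changed 2-fold and 96.0% of genes changed 4-fold, and 4.95% of its calls were false. The corresponding shares were 55.0%, 88.0% and 7.01% for Rar mutants, 39.0%, 89.0% and 3.68% for Dmrt1 het Rar mutants, and 36.0%, 80.0% and 6.40% for the difference between the 2 kinds of Rar-deleted ovary. The spread simulated came from a fit with the title-number batch, described below, as a term, and no batch effect was simulated. The changed genes were drawn from those with a mean CPM above 1. These shares therefore do not cover the batch difference, which the main fits leave in the spread.

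The tests, the gene lists, the other settings to try and the rule for named genes were set before the data were examined. The rule named, for each comparison, Rara, Rarb, Rarg, Dmrt1 and Nr5a1. It added the 12 highest and the 12 lowest fold changes among called genes whose case libraries all lay on 1 side of the control mean. Where fewer than 10 genes were called, it took every called gene and the 5 uncalled genes with the smallest p. From each list it took members past the threshold adjusted over the list alone, otherwise up to 3 members with the smallest p, and from the authors' table the 5 highest and 5 lowest fold changes. Predicted genes were counted, and named only where fewer than 10 others passed. Where these lists gave many genes, a part is printed.

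The sample titles carry numbers from 7558 to 7807. The 4 libraries with numbers under 7800 (control 1, Rar mutant 1 and both Dmrt1 het Rar mutants) stood apart from the 6 with higher numbers, so that boundary is treated as a possible batch. An analysis of the higher numbers alone was planned, and a batch term in the fit was added after the data were seen. The other alternatives were DESeq2 1.42.0 (size factors, and its Wald test), limma-voom, edgeR without robust estimation, no or a stricter low-count filter (a mean CPM of 1), and limma-trend on log2 FPKM with pseudocounts of 1 and 0.1. Further ones were a surrogate variable from sva 3.50.0, an adjusted p under 0.1, each library left out in turn, an equal-weight mean of the Rar-deleted groups and separate 2-group fits. Chosen after the data were seen were the batch term without Rar mutant 3 and a DESeq2 fit with shrunken fold changes made as in the authors' table. Random gene lists (10000 draws from 50 expression bins, and for the title-number batch also from 20 expression bins by 5 exon length bins) gave the reference for list medians in the closing tests. No library was left out of the main comparisons. The value of 1 gene that passed a threshold adjusted over its list alone is not reported here.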

Results

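Gene expression was measured by polyA RNA sequencing in 10 mouse ovary samples at 6 weeks of age: 5 controls, 3 Rar mutants and 2 Dmrt1 het Rar mutants. Both mutant groups carried Sf1-Cre and floxed Rara, Rarb and Rarg, the genes of the nuclear receptors for retinoic acid. The study's title and labels set the question of what somatic cells of the ovary need retinoic acid receptors for. Libraries held 21064856 to 25920131 counts.

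Along the first principal component (35.5% of the variance of log2 CPM over 18954 genes), the 4 libraries with title numbers under 7800 lay from -49.3 to -40.0 and the other 6 from 2.80 to 52.9. In a fit with a term for Rar-deleted against control but none for Dmrt1 het status, 5250 genes differed between these sets of libraries. Of these, which may include Dmrt1 het differences, 2703 were higher and 2547 lower in the lower numbers. Markers of surface epithelium were lower there by a median log2 difference of -0.90, with 8 of 12 called lower and 2 called higher. Erythroid genes had a median of -1.80, with 5 of 5 called lower, and oocyte genes had a median of -0.56, with 7 of 23 called lower. Random lists matched for expression and exon length had medians of -0.09 for surface epithelium, -0.56 for erythroid and -0.29 for oocyte genes. Part of the erythroid and oocyte differences may thus go with expression level or exon length. The lower numbers comprised 1 control, 1 Rar mutant and both Dmrt1 het Rar mutants, so the numbers of called genes and lists in each comparison are given below with the batch as a term too.

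**Figure D1:**
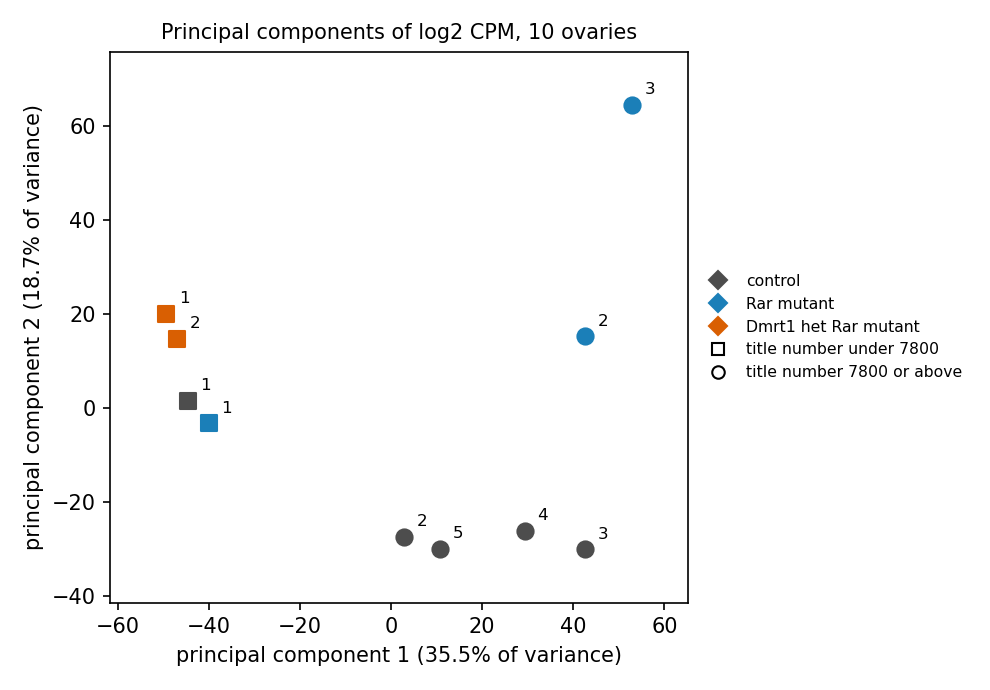
Principal components 1 and 2 of log2 CPM for the 10 libraries, with the percent of variance on each axis; colour gives the group and the marker shape gives the title number (squares under 7800, circles 7800 or above). The squares lie at -40.0 or below on component 1, and Rar mutant 3 lies at 64.6 on component 2.

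The first question was whether transcripts of the targeted genes differed in the mutants. Rarg (ENSMUSG00000001288, GRCm38 chromosome 15, 102234938 to 102257517) had 18.8 ± 2.67 CPM in the 5 Rar-deleted ovaries and 29.4 ± 3.51 CPM in the 5 controls. Its log2 fold change was -0.64 (SE 0.14, edgeR adjusted p = 0.190), below the control mean in 5 of 5. Rara (ENSMUSG00000037992, chromosome 11, 98927818 to 98974942) had 27.8 ± 4.02 against 25.7 ± 6.36 CPM, a log2 fold change of 0.11 (SE 0.18, adjusted p = 0.848). Rarb (ENSMUSG00000017491, chromosome 14, 16430839 to 16819156) had 2.52 ± 0.298 against 3.11 ± 0.824 CPM, a log2 fold change of -0.31 (SE 0.21, adjusted p = 0.659). Nr5a1 (ENSMUSG00000026751, chromosome 2, 38692656 to 38714542), the gene whose promoter drives the Cre, had 332 ± 57.2 against 206 ± 60.8 CPM, with a log2 fold change of 0.68 (SE 0.21, adjusted p = 0.450). Dmrt1 (ENSMUSG00000024837, chromosome 19, 25505618 to 25604329) had 0 counts in 9 libraries and 5 counts in Dmrt1 het Rar mutant 2, so its loss was not detectable at this depth. Of the 4 tested genes edgeR called 0, with 2 (Rarg and Nr5a1) at an unadjusted p under 0.05, while DESeq2 called 1, Rarg, with an adjusted p of 0.00419. Whole-gene counts do not separate the floxed exons from the rest of a transcript, nor the cells with Cre from those without.

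The comparison of all 5 Rar-deleted ovaries with 5 controls asked which genes differed when retinoic acid receptors were deleted. Tdh, which encodes the threonine dehydrogenase of mitochondria (ENSMUSG00000021953, chromosome 14, 63492347 to 63509092), rose 12.9-fold, from 0.724 ± 0.222 to 9.45 ± 3.42 CPM. Nr6a1, the orphan receptor known as germ cell nuclear factor (ENSMUSG00000063972, chromosome 2, 38723370 to 38927688), rose 3.68-fold, from 13.0 ± 2.34 to 48.0 ± 10.6 CPM, and lies beside Nr5a1. Eef1a2, a translation elongation factor, rose from 0.506 ± 0.196 to 3.10 ± 0.992 CPM, and Scn3b, a sodium channel subunit, from 2.0 ± 0.71 to 8.0 ± 2.07 CPM. St14, which encodes the epithelial membrane protease matriptase, fell from 5.31 ± 2.25 to 1.03 ± 0.142 CPM, and Ocln, which encodes the tight junction protein occludin, fell from 3.64 ± 0.796 to 1.29 ± 0.293 CPM. The lipid receptor gene Gpr55 was 14.7-fold lower and Sectm1b 9.99-fold lower, Anpep, which encodes aminopeptidase N, fell from 43.7 ± 16.6 to 15.7 ± 2.73 CPM, and Plekha6 fell from 16.7 ± 2.25 to 7.08 ± 0.684 CPM.

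In edgeR, 21 of 18954 genes were called in that comparison, 4 higher and 17 lower, and 20 of them had an absolute log2 fold change of at least 1. Log2 fold changes of the higher genes were 3.69 for Tdh (SE 0.31, adjusted p = 0.00170), 2.59 for Eef1a2 (SE 0.33, adjusted p = 0.0161), 1.99 for Scn3b (SE 0.29, adjusted p = 0.0295) and 1.88 for Nr6a1 (SE 0.19, adjusted p = 0.00423). Among lower genes they were -3.88 for Gpr55 (SE 0.42, adjusted p = 0.00481), -3.32 for Sectm1b (SE 0.43, adjusted p = 0.0161), -2.36 for St14 (SE 0.31, adjusted p = 0.0161) and -1.24 for Plekha6 (SE 0.14, adjusted p = 0.00645). The other named lower genes ran from -2.53 for Cnksr1 to -1.48 for Anpep, with Slc27a2 at -2.25, Atp6ap1l at -2.22, Ccdc64b at -2.01, Grb7 at -1.81, Lmntd1 at -1.53 and Ocln at -1.5. All libraries of the Rar-deleted group lay on 1 side of the control mean for 21 of the 21 genes. Grb7 lies within 1000 kb of Rara and was the 1 called among 34 tested genes there. DESeq2 called 168 genes, with all 21 among them. With the batch as a term 40 genes were called, 18 of the 21 among them (Anpep, Grb7 and Lmntd1 were not), and in the 6 libraries of higher title number (2 Rar mutants against 4 controls) 142 were called, 9 of the 21 among them. Tdh, Nr6a1, Gpr55 and Plekha6 passed whichever library was left out, whereas the total was 52 without control 1, 11 without control 2, 7 without control 3, 5 without control 4, 8 without control 5, 5 without Rar mutant 2, 6 without Dmrt1 het Rar mutant 1 and 5 without Dmrt1 het Rar mutant 2. With the batch as a term and without Rar mutant 3, 2 genes were called.

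**Figure D2:**
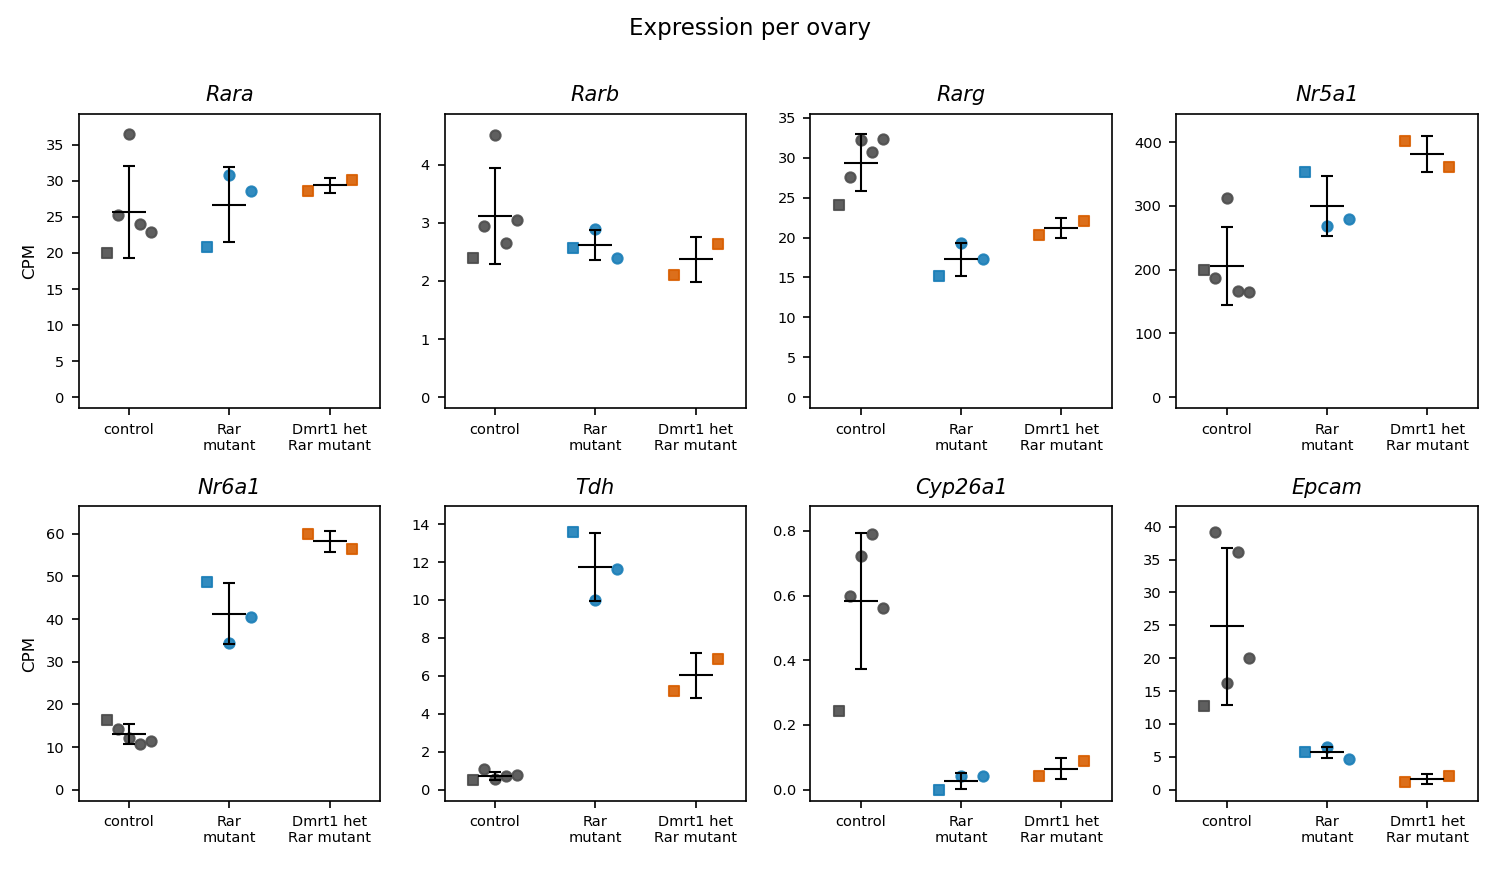
CPM of 8 genes in each of the 10 ovaries by group, with bars for mean ± SD; squares are title numbers under 7800 and circles are 7800 or above. Nr6a1 was at 34.5 CPM or above in the Rar-deleted ovaries and at 16.4 CPM or below in controls, and Cyp26a1 was at 0.0880 CPM or below in every Rar-deleted ovary.

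Among the 24 gene lists, 7 passed camera in that comparison, and 6 with the batch as a term, 5 of the 7 among them. With an estimated correlation 0 passed, whether or not the batch was a term. Retinoic acid responsive genes were lower as a list (12 measured, median log2 fold change -0.27, adjusted p = 0.0247, and adjusted p = 0.244 with an estimated correlation). The low-count filter of this fit left out Cyp26a1, so the 12 do not include it, and its counts are given below for each mutant group. No measured member was called over all genes, and 3 were lower adjusted over the list alone. These were Lrat, which stores retinol as esters (-2.04, SE 0.38, 6.02 ± 2.32 against 24.5 ± 12.7 CPM), Hsd17b2, which inactivates oestradiol (-2.12, SE 0.39, 2.20 ± 1.55 against 9.55 ± 2.03 CPM), and Rarres2, which encodes chemerin (-0.63, SE 0.19). This list's adjusted p was 0.0772 with the batch as a term, 0.0567 with a surrogate variable and 0.0592 without control 3. Genes of retinoic acid synthesis, transport and receptors gave an adjusted p of 0.927 (14 measured, median 0.02).

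The list of oviduct and ciliated epithelium was lower (10 measured, median -0.38, adjusted p = 0.0180, and adjusted p = 0.244 with an estimated correlation). Adjusted over the list alone, 3 members were lower and 1 higher. The lower ones, which epithelia in general express, were the adhesion genes Epcam (-2.61, SE 0.47) and Cdh1 (-1.40, SE 0.27) and the secreted protein gene Wfdc2 (-1.99, SE 0.59); the higher one was the oviduct glycoprotein gene Ovgp1 (2.27, SE 0.75). Epcam had 4.06 ± 2.32 CPM in Rar-deleted ovaries and 24.9 ± 12 CPM in controls. Ovarian surface epithelium was also lower as a list, with 12 of 12 fold changes negative and 0 called by edgeR over all genes or adjusted over the list alone (median -0.36, adjusted p = 0.00204, and adjusted p = 0.579 with an estimated correlation). Its smallest p belonged to Lrrn4 (-0.95, SE 0.29), Krt7 (-1.51, SE 0.50) and Msln (-0.80, SE 0.29). It was also lower in the libraries of lower title number, as given above, and its adjusted p was 0.0183 with the batch as a term. The oviduct list gave 0.426 without Rar mutant 2, 0.150 without control 2, 0.159 without Rar mutant 3, 0.0592 without control 3, 0.0746 without control 4, 0.113 without control 5, and 0.283 with no low-count filter.

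Oocyte genes were lower, with 23 of 23 fold changes negative and 0 called (median -0.39, adjusted p = 2.29e-05, and adjusted p = 0.659 with an estimated correlation), but gave an adjusted p of 0.0688 with the batch as a term. Endothelial genes were lower as a list (10 measured, median -0.14, adjusted p = 0.0455, and adjusted p = 0.659 with an estimated correlation), with 1 member past the threshold adjusted over the list alone, the tight junction gene Cldn5 (-0.75, SE 0.13). Without Dmrt1 het Rar mutant 1, control 1, Rar mutant 2 or Rar mutant 3, the endothelial list gave 0.151, 0.433, 0.0833 and 0.159. Genes of ovulation and cumulus expansion were higher (11 of 11 positive, 9 past the threshold adjusted over the list alone, median 2.82, adjusted p = 0.000265, and adjusted p = 0.624 with an estimated correlation). Rar mutant 3 carried much of this: without it the prostaglandin synthase gene Ptgs2 was at 1.95 instead of 6.70 (SE 1.85), the progesterone receptor gene Pgr at 0.34 instead of 4.23 (SE 1.36), and the list at an adjusted p of 0.0269. Immediate early genes were higher too (13 of 14 positive, 0 past either threshold, median 1.08, adjusted p = 0.00806, and adjusted p = 0.664 with an estimated correlation), but gave 0.727 without Rar mutant 3. The fry test passed for 3 lists, those of retinoic acid responsive genes (0.0217), oviduct and ciliated epithelium (0.00248) and genes beside Nr5a1 (0.0205).

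The other 17 lists did not pass camera. Adjusted p was 0.0504 for adipocyte, 0.0638 for interferon response, 0.134 for erythroid, 0.190 for genes beside Nr5a1, 0.228 for Sertoli cell and testis fate, 0.425 for ovarian somatic fate, cholesterol synthesis and cell proliferation, and 0.466 for granulosa cell, corpus luteum and B and plasma cell. It was 0.785 for theca cell, 0.885 for steroidogenesis, 0.944 for meiotic prophase and smooth muscle, and 0.969 for macrophage. Members of these past the threshold adjusted over the list alone were Nr0b1, a repressor of Nr5a1 activity (-1.36, SE 0.33), Cyp11b1, a steroid hydroxylase (5.71, SE 1.54), the adipocyte genes Car3 (-2.30, SE 0.64) and Cfd (-3.05, SE 1.07), and Nr6a1 and Nr5a1 among the genes beside Nr5a1. Cyp11b1 was at 49.8 CPM in Rar mutant 2, 12.5 in Rar mutant 3 and 2.45 in Rar mutant 1. In the Dmrt1 het Rar mutants Cyp11b1 was at 0.0839 and 0.220 CPM, within the 0 to 0.598 of controls.

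On chromosome 2, Nr6a1 and Nr5a1 lie next to each other, with the pseudogene Adgrd2-ps and the antisense gene Nr5a1os, both named after their values were seen. Adgrd2-ps had a log2 fold change of 1.68 (SE 0.35, adjusted p = 0.142) and Nr5a1os of 1.30 (SE 0.42, adjusted p = 0.491), neither called. The lowest Rar-deleted ovary exceeded the highest control for Nr6a1 (5.11 against 4.05 log2 CPM) and, narrowly, for Adgrd2-ps (0.36 against 0.11) and Nr5a1os (0.30 against 0.28). For Nr5a1 it did not (8.06 against 8.28, the latter in control 3). Farther neighbours had log2 fold changes of 0.37 (Nek6, SE 0.16), 0.00 (Psmb7, SE 0.15), -0.38 (Gm13588, SE 0.42) and -0.49 (Gm13586, SE 0.29), and Nr6a1os, which lies within Nr6a1, had -0.17 (SE 0.33), none of them called. Every Rar-deleted ovary and no control carried the Cre, so Cre and receptor loss coincide in these data.

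**Figure D3:**
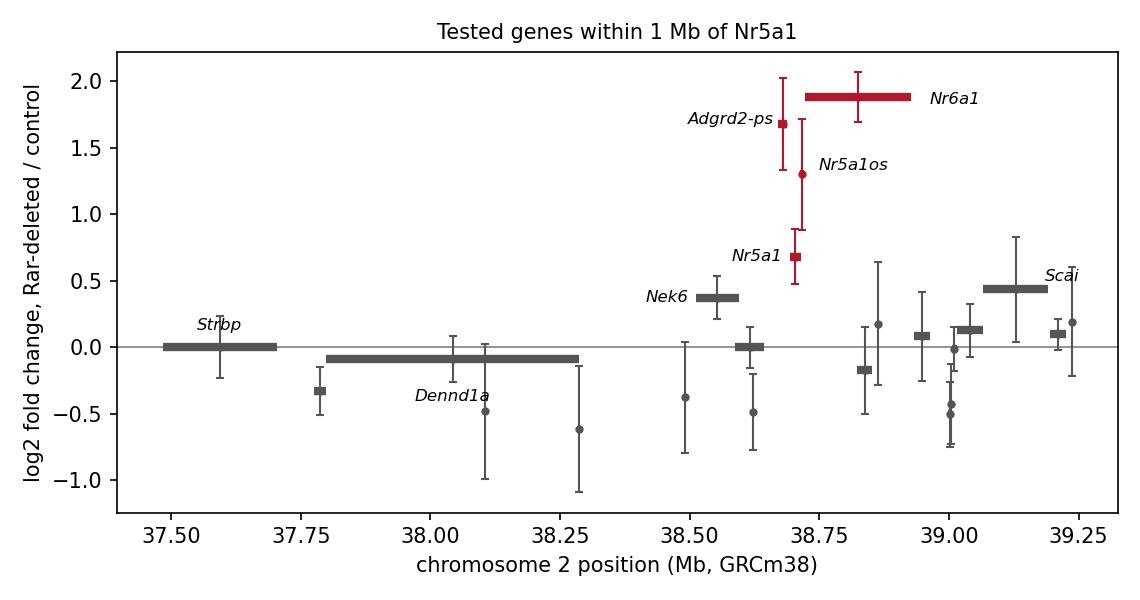
Log2 fold change ± SE (all Rar-deleted ovaries against control) of the tested genes within 1000 kb of Nr5a1 on chromosome 2, by position on GRCm38. Nr6a1 stands at 1.88, Adgrd2-ps at 1.68, Nr5a1os at 1.30 and Nr5a1 at 0.68, and of these only Nr6a1 was called.

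The comparison of 3 Rar mutants with 5 controls isolates the genotype without a floxed Dmrt1 allele. Tdh rose 15.9-fold to 11.7 ± 1.80 CPM (log2 4.0, SE 0.25, adjusted p = 0.000154) and Nr6a1 rose 3.15-fold to 41.2 ± 7.10 CPM (log2 1.65, SE 0.17, adjusted p = 0.00929). Cyp26a1, whose product degrades retinoic acid, had counts of 0, 1 and 1 in the mutants and 6 to 20 in controls, lower adjusted over the list alone. In the same list, Lrat (-2.02, SE 0.47) and Hsd17b2 (-1.77, SE 0.40) were lower by that test. Adh7, a retinol-oxidising alcohol dehydrogenase, had 20.5 ± 6.69 against 2.59 ± 1.92 CPM (log2 2.97, SE 0.50), higher adjusted over the list alone. Among uncalled genes of smallest p, Pappa2, a protease of insulin-like growth factor binding proteins, had 12 ± 9.86 against 0.472 ± 0.409 CPM (log2 4.65, SE 0.65, adjusted p = 0.0557), and Gpr55 (-3.79), Gm19410 (-3.54), Sez6l (2.01) and Plekha6 (-1.21) had the same adjusted p.

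Those 2 genes were the calls of edgeR among 20570, both higher, with 1944 genes at an unadjusted p under 0.05, and DESeq2 called 374. With the batch as a term 85 genes were called (59 higher, 26 lower), and in the 6 libraries of higher title number 142 (118 higher, 24 lower). Leaving out Rar mutant 1 gave 384 calls and leaving out control 2 gave 7, whereas Nr6a1 was lost and 1 call stayed without Rar mutant 3, control 3 or control 5, as in a fit of the 2 groups alone. Rarg had a log2 fold change of -0.78 (SE 0.15, adjusted p = 0.104), and -0.73 with an adjusted p of 0.0350 with the batch as a term.

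Genes of ovulation and cumulus expansion were higher in Rar mutants as a list (14 of 14 positive, median 4.52, adjusted p = 9.23e-09, and adjusted p = 0.338 with an estimated correlation), and 13 passed adjusted over the list alone. They include Ptgs2, which makes prostaglandins (7.42, SE 1.51), the progesterone receptor Pgr (4.93, SE 1.17), the growth factor genes Ereg (6.92, SE 1.41) and Btc (5.60, SE 1.15), and Tnfaip6, which stabilises the cumulus matrix (5.96, SE 1.31). Most of the counts came from Rar mutant 3. Ptgs2 had 4875 counts there, 98 in Rar mutant 2, 8 in Rar mutant 1 and 3 to 18 in controls. Sult1e1, which sulfates oestrogen, had 24572 counts in Rar mutant 3, 24 in Rar mutant 2 and 0 to 5 in every other library. Akr1b7, a detoxifying reductase of steroidogenic tissue named after its values were seen, had 5973 counts in Rar mutant 2, 6081 in Rar mutant 3 and 6 to 19 elsewhere. The list's adjusted p was 0.000779 without Rar mutant 3. Without Rar mutant 3 the fold changes of Ptx3 (2.86, SE 0.97), another matrix gene, and of Egr2 (2.80, SE 0.91) and Egr3 (2.74, SE 0.98), immediate early genes, were -1.03, -0.26 and -0.45, and without Rar mutant 2 that of Edn2 (3.22, SE 1.15) was -0.65.

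**Figure D4:**
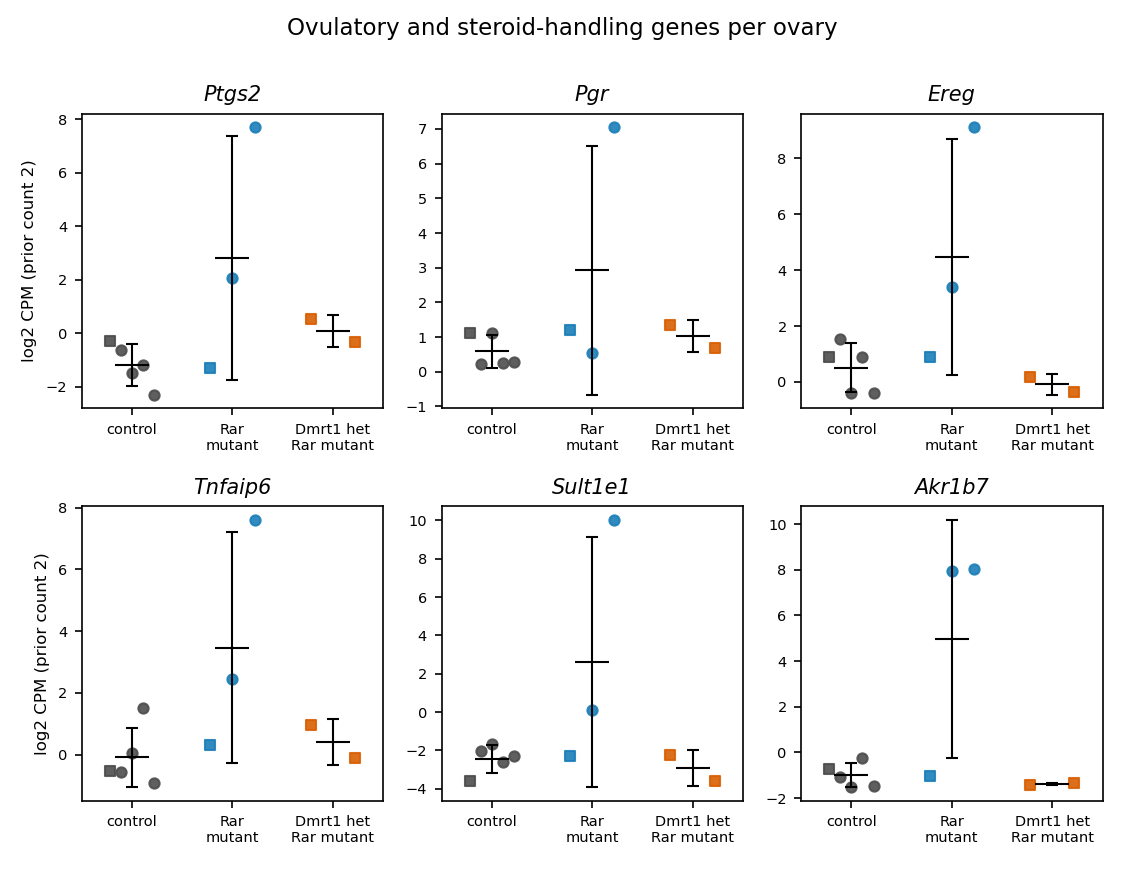
Log2 CPM (prior count 2) of Ptgs2, Pgr, Ereg, Tnfaip6, Sult1e1 and Akr1b7 in each of the 10 ovaries by group; squares are title numbers under 7800 and circles are 7800 or above. Rar mutant 3 is highest for each gene, and Rar mutant 2 stands with it for Akr1b7.

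Of the 24 lists, 8 passed camera for Rar mutants, the same 8 with the batch as a term, and 0 with an estimated correlation, for which the smallest adjusted p was 0.338. With fry 3 passed, 1 of the 8 among them. Steroidogenesis genes were higher (14 measured, median 0.37, adjusted p = 0.00466, and adjusted p = 0.338 with an estimated correlation), with Cyp11b1 (6.44, SE 0.98) and the electron carrier gene Fdx1 (1.02, SE 0.28) past the threshold adjusted over the list alone. Cholesterol synthesis genes were higher (17 of 20 positive, 0 past either threshold, median 0.48, adjusted p = 0.000359, and adjusted p = 0.343 with an estimated correlation). Granulosa cell genes were lower (17 of 18 negative, median -0.38, adjusted p = 0.000359, and adjusted p = 0.338 with an estimated correlation), with Nr0b1 (-1.70, SE 0.37) and Hsd17b1, which makes oestradiol (-0.78, SE 0.22), past the list threshold. Erythroid genes were higher (6 of 6 positive, median 1.30, adjusted p = 0.000359, and adjusted p = 0.343 with an estimated correlation), with Alas2, Hbb-bs and Hbb-bt past the list threshold. Immediate early genes were higher (7 of 14 past the list threshold, adjusted p = 0.00194, and adjusted p = 0.567 with an estimated correlation), but had the opposite direction and 0.377 without Rar mutant 3. Oocyte genes were lower (23 of 23 negative, 0 past either threshold, adjusted p = 0.000150, and adjusted p = 0.567 with an estimated correlation), with the opposite direction and 0.752 without Rar mutant 1. Retinoic acid responsive genes were lower (14 measured, median -0.24, adjusted p = 0.0255, and adjusted p = 0.338 with an estimated correlation), with 0.102 without Rar mutant 1, 0.0562 without control 3 and 0.0774 with no low-count filter. The steroidogenesis list gave 0.213 without Rar mutant 1. Runx1 (2.01, SE 0.49) and Irx3 (-0.71, SE 0.15), transcription factor genes of the somatic ovary, passed the list threshold in a list that did not pass camera (ovarian somatic fate, adjusted p = 0.347).

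The authors' deposited table covers the same Rar mutants and controls with 185 genes, 136 higher and 49 lower, and is thus not independent of the values above. In the authors' deposited table, whose log2 fold changes are shrunken, Tdh was highest at 3.33 (SE 0.234, adjusted p = 1.09e-41), followed by Pappa2 (2.28), Prph (1.97), Sv2c (1.87) and Eef1a2 (1.87). The lowest in the authors' deposited table were Gm19410 (-2.16), Gpr55 (-2.14), Sectm1b (-1.91), Cnksr1 (-1.76), St14 (-1.59) and Epcam (-1.53). The edgeR fit tested 184 of these genes, and 184 had the same sign there and an unadjusted p under 0.05, while 2 were called and 49 with the batch as a term. A DESeq2 fit with shrunken fold changes on those 8 libraries called 187 genes beyond an absolute log2 fold change of 1, of which 176 are in the table.

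The genes of that table were not spread evenly over the mutants. For the 136 higher genes, the median log2 difference from the control mean was 2.62 in Rar mutant 3, 1.94 in Rar mutant 2 and 0.70 in Rar mutant 1, and 102 of them were highest in Rar mutant 3. In the Dmrt1 het Rar mutants, which the table does not use, it was 0.24 and 0.34, and in controls it ran from -0.18 to 0.19. For the 49 lower genes the medians were -1.53, -1.72 and -1.64 in Rar mutants 1, 2 and 3 and -1.46 and -1.65 in the Dmrt1 het Rar mutants, whereas controls lay between -0.40 and 0.20. The table's genes were chosen on the Rar mutants and controls, so the medians in those libraries are not independent evidence of direction.

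**Figure D5:**
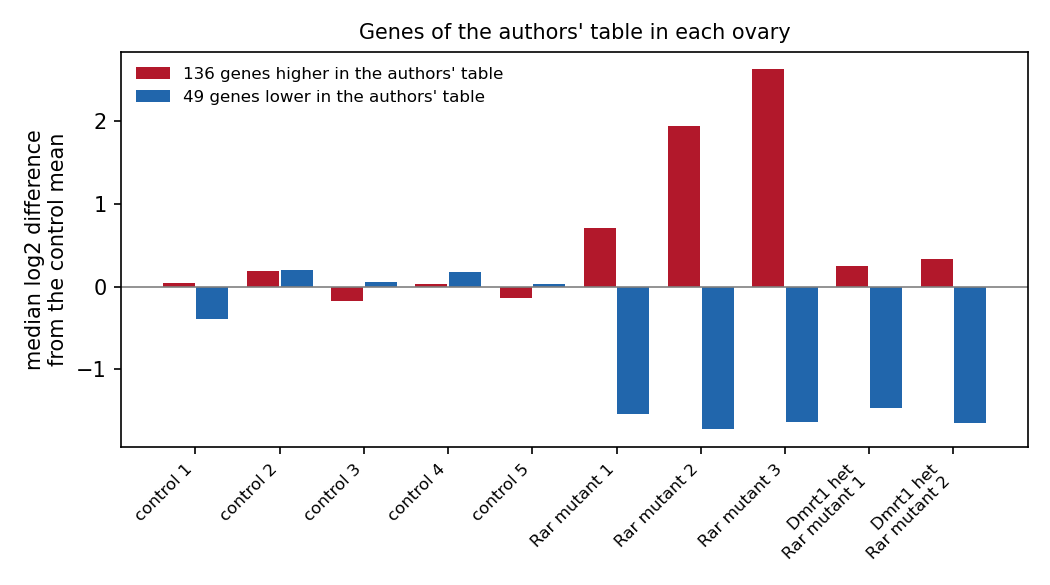
Median log2 difference from the control mean, in each of the 10 ovaries, of the 136 genes higher and the 49 genes lower in the authors' table. The lower genes stand between -1.72 and -1.46 in all 5 Rar-deleted ovaries, and the higher genes between 0.24 and 2.62.

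The comparison of 2 Dmrt1 het Rar mutants with 5 controls covers the Cre, the receptor loss and the floxed Dmrt1 allele together. It does not isolate that allele. Nr6a1 rose 4.46-fold to 58.2 ± 2.49 CPM (log2 2.16, SE 0.18, adjusted p = 0.00249) and Tdh rose 8.23-fold to 6.03 ± 1.18 CPM (log2 3.04, SE 0.27, adjusted p = 0.00249). Neb, which encodes the muscle protein nebulin, rose from 13.4 ± 3.18 to 49.98 ± 4.32 CPM (log2 1.89, SE 0.23, adjusted p = 0.0237). Gpc3, a cell-surface proteoglycan, fell from 58.1 ± 7.17 to 21.9 ± 1.90 CPM (log2 -1.41, SE 0.17, adjusted p = 0.0237). Of uncalled genes with the smallest p, Epcam had 1.64 ± 0.724 against 24.9 ± 12 CPM (log2 -3.92, SE 0.54, adjusted p = 0.0625), Prr15l a log2 fold change of -2.47 and Sectm1b of -4.11, Eef1a2 of 2.67 and Plekha6 of -1.31.

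These 4 genes were all the edgeR calls among 20570 tested (3 higher, 1 lower), while 346 were called by DESeq2. Both Dmrt1 het libraries have title numbers under 7800, with 1 control and 1 Rar mutant beside them, so a fit within those libraries has no replicate control. Without that control, control 1, the comparison coincides in full with the title-number batch, so calls made then cannot be credited to genotype. With the batch as a term, Nr6a1 was the 1 call (log2 1.85), and Tdh (3.07), Neb (1.62) and Gpc3 (-1.29) did not pass. Leaving out control 1 gave 364 calls, whereas there were 2 without control 2, control 3 or control 5, 1 without Dmrt1 het Rar mutant 1 and 0 without Dmrt1 het Rar mutant 2.

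Of the 24 lists, 4 passed camera in this comparison, all lower, and 3 passed fry, 2 of the 4 among them. With an estimated correlation 0 passed camera, whether or not the batch was a term. With the batch as a term 13 passed camera, 6 higher and 7 lower, and 1 passed without control 1, 8 without Dmrt1 het Rar mutant 2 and 7 without control 4. Surface epithelium was lower in these ovaries, with 8 of 12 members lower adjusted over the list alone (median -0.97, adjusted p = 0.000154, and adjusted p = 0.367 with an estimated correlation). They included the keratins Krt7 (-2.78, SE 0.60), Krt19 (-2.40, SE 0.49) and Krt18 (-1.82, SE 0.50) and the mesothelial antigen gene Msln (-1.47, SE 0.33). The same list had a median of -0.90 in the libraries of lower title number, which include both of these ovaries. These values, from fits without a batch term, thus do not separate genotype from batch. Retinoic acid responsive genes were lower (adjusted p = 0.0398, and adjusted p = 0.367 with an estimated correlation), with 5 of 14 lower adjusted over the list alone. They included Hsd17b2 (-2.91, SE 0.52), Lrat (-2.06, SE 0.56), Rarres2 (-0.91, SE 0.24) and Cyp26a1, with 1 and 2 counts. Steroidogenesis genes were lower (14 of 14 negative, 0 past either threshold, median -0.49, adjusted p = 0.0398, and adjusted p = 0.739 with an estimated correlation). Oocyte genes were lower (22 of 23 negative, 0 past either threshold, adjusted p = 0.0398, and adjusted p = 0.812 with an estimated correlation), and had the opposite direction with the batch as a term (0.00907) and with a surrogate variable (0.973), and gave 0.758 with equal replicate numbers as a block. The retinoic acid list gave 0.0659, 0.0664 and 0.0512 without Dmrt1 het Rar mutant 1, control 1 or control 3. The steroidogenesis list gave 0.218, 0.0670 and 0.0557 without Dmrt1 het Rar mutant 1, control 1 or control 2, and the oocyte list 0.0664, 0.196 and 0.0621 without control 1, Dmrt1 het Rar mutant 2 or control 5.

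The 2 kinds of Rar-deleted ovary were compared to see whether they could be told apart. edgeR called 0 of 20570 genes (smallest adjusted p 0.111), with 3467 at an unadjusted p under 0.05, and DESeq2 called 682. The genes of smallest p were Neb (log2 1.91, SE 0.26, 49.98 ± 4.32 against 13.3 ± 2.04 CPM), Ank3, which encodes a membrane scaffold (1.48, SE 0.20), the potassium channel gene Kcnq5 (1.80, SE 0.25), Tox2 (1.5, SE 0.22) and Gm30292 (1.74, SE 0.25), all higher in Dmrt1 het Rar mutants in 2 of 2 libraries. Granulosa cell genes were higher there as a list (16 of 18 positive, median 0.78, adjusted p = 5.85e-05, and adjusted p = 0.405 with an estimated correlation). Adjusted over the list alone 6 passed, with the follicle-stimulating hormone receptor Fshr (1.58, SE 0.41), the oestrogen receptor Esr2 (1.32, SE 0.22) and Bmpr1b (1.16, SE 0.23) among them. Steroidogenesis genes were lower (14 of 14 negative, median -0.99, adjusted p = 7.93e-05, and adjusted p = 0.405 with an estimated correlation), with 5 past the threshold adjusted over the list alone, among them Fdx1 (-1.65, SE 0.37) and Por (-1.26, SE 0.42). Adh7 (-3.01, SE 0.71) and Rbp4 (-2.28, SE 0.55), a retinol transport gene, were lower adjusted over the list alone. Both Dmrt1 het Rar mutants but only 1 of 3 Rar mutants had title numbers under 7800, and with the batch as a term edgeR again called 0 (1770 at an unadjusted p under 0.05). Without Rar mutant 1, the 1 Rar mutant of lower title number, 335 genes were called. That comparison then coincided in full with the batch.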

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

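Chosen only after their results were seen were the tests of surface epithelium in the batch, of the Nr5a1 region, of the cycle stage and of the batch in the genes of the authors' table, and the fits with the batch as a term; those of gene length and of adrenal tissue were set earlier.

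Granulosa cell genes were higher, and genes of hormone and cholesterol synthesis lower, in Dmrt1 het Rar mutants (n = 2) than in Rar mutants (n = 3), which is also the test of whether the effects of these genotypes against control differ. The camera adjusted p was 5.85e-05 for granulosa cell genes and 7.93e-05 for steroidogenesis (each 0.405 with an estimated correlation). It was 0.000228 for cholesterol synthesis, and 0.537 with an estimated correlation (18 of 20 negative, median -0.74, smallest p for Msmo1 at -1.19, SE 0.32, and Cyp51 at -1.62, SE 0.50, enzymes of the late pathway). Ovulation and cumulus expansion (14 of 14 negative, median -4.27) gave 0.00142, and 0.703 with an estimated correlation, with 10 members past the threshold adjusted over the list alone. Ovarian surface epithelium (10 of 12 negative, median -0.97) gave 0.00405, and 0.537 with an estimated correlation, with 7 past it, such as Krt19 (-1.77, SE 0.50) and Cldn15 (-1.17, SE 0.32). Erythroid genes (6 of 6 negative, median -1.81) gave 0.00669, with Hbb-bs, Hbb-bt and Alas2 past it, and smooth muscle genes (8 of 8 negative, median -0.87) gave 0.0103 (each 0.677 with an estimated correlation). No list passed with an estimated correlation (0 of 24, smallest adjusted p = 0.405) or with fry (0 of 24), against 7 of 24 for camera and 7 for camera with the batch as a term, 5 of the first 7 among them. Both Dmrt1 het Rar mutants but only 1 of 3 Rar mutants have low title numbers. Between libraries of low and high number the medians of these 7 lists had the same signs, such as 0.37 for granulosa cell genes and -0.33 for steroidogenesis. Ovulation genes gave 0.131 without Rar mutant 3, 0.0570 with a surrogate variable and 0.0797 with the batch as a term. Smooth muscle genes gave 0.104 without Dmrt1 het Rar mutant 1 and 0.0518 without Rar mutant 3, and erythroid genes gave 0.104, 0.0506 and, with the batch as a term, 0.181.

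Single libraries stood apart from their group for 13 of 202 values tested (5 Rar-deleted or 5 control libraries each), where chance would give 10.1; each was picked out by the gap to its nearest neighbour as a share of the group's range. In Rar mutant 3 the share was 0.745 for Has2, 0.874 for Pgr, 0.781 for Btc, 0.877 for Ptx3 and 0.729 for Sult1e1, all genes of ovulation with values above the other Rar-deleted ovaries. In control 1 it was 0.720 for Hsd17b2, 0.859 for Wfdc2 and 0.740 for Cldn15, all below the other controls, and 0.744 for Egr2, above them. In control 3 it was 0.713 for Nr5a1 and 0.821 for Cldn5, both above the other controls. Rara was lowest in Rar mutant 1, with a share of 0.814. Dmrt1 had its 5 counts in Dmrt1 het Rar mutant 2 alone, for a share of 1.

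The 4 libraries with title numbers under 7800 differed from the other 6 in 5250 genes, more than in any comparison of genotypes. Both Dmrt1 het Rar mutants are among the 4, and their Dmrt1 status was not a term, so its effect is not separated from the batch. Fold changes between these sets rose with gene length: the Spearman correlation across 14995 genes was 0.559, and the median log2 difference ran from -0.47 in the 2999 shortest (median exon length 1040 bases) to 0.41 in the 2999 longest (9603 bases). Surface epithelium genes were lower in the same libraries by a median of -0.899. Length alone is no account of that, since 10000 random lists matched for expression and length had a median of -0.0866 and none lay as low, but the lists of ovulation (-2.05, with most counts in Rar mutant 3), erythroid (-1.80), smooth muscle (-0.76) and immediate early genes (-0.68) also lay below all of theirs. The granulosa cell list, at 0.37, lay above all of its random lists, whose median was -0.16. A difference in library making that favours long transcripts is a candidate explanation for the trend with length. A smaller amount of surface epithelium at dissection was proposed from the value that tests it, so it stays open and cannot be told apart from other differences between these sets of animals. The labels name no batch or dissection day, and no other explanation was tested.

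Nr6a1 was called higher in Rar-deleted ovaries, and beside it on chromosome 2 Adgrd2-ps and Nr5a1, neither called, had log2 fold changes of 1.68 (SE 0.35) and 0.68 (SE 0.21). The title-number batch as the whole cause is argued against for Nr6a1, whose log2 fold change was 1.88 (SE 0.19) without and 1.67 with the batch as a term, the latter with an adjusted p of 0.000795. A Cre transgene built on the Nr5a1 promoter may carry extra copies of neighbouring sequence. The median log2 fold change of the 11 tested genes within 250 kb of Nr5a1 was 0.178, higher than 92.2% of random lists. It lies between the limits set, after the values were seen, for extra copies of that whole stretch and for none. The 11 include Nr6a1, Adgrd2-ps and Nr5a1, whose values prompted the idea, so this median cannot decide the question. An effect of receptor loss on these genes also stays open, since every Rar-deleted ovary and no control carried the Cre, so the causes cannot be told apart here.

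The 136 genes higher in the authors' table were raised mostly in Rar mutants 2 and 3. Adrenal tissue in these samples is argued against by Cyp21a1, abundant in adrenal cortex, which was at 0.0414 CPM in Rar mutant 2, the higher of these libraries, and at 5 counts or fewer in every library. Other genes of adrenal cortex were high in Rar mutants 2 and 3: Cyp11b1 at 49.8 and 12.5 CPM against at most 0.598 in controls, Cyp11b2 at 25 and 8 counts against at most 1, Mrap at 285 and 529 CPM against 28.1 to 110, and Akr1b7 as given above. The receptor gene Mc2r was not, at 0.166 and 0.0427 CPM against 0.120 to 0.181 in controls. Adrenal cells would bring Cyp21a1 along with them, so a source of these transcripts other than adrenal tissue stays open. The batch alone is argued against by the 6 libraries of high title number, which share it. Over all genes, 118 were called higher there in Rar mutants 2 and 3 than in controls 2 to 5, 69 of the 136 among them. The genes of the authors' table were chosen partly on these 6 libraries, so the 69 are not independent evidence. Only the calls over all genes bear on the batch. A different stage of the ovarian cycle in these animals may account for part of the pattern: the median in Rar mutant 1 was 0.308 of that in Rar mutants 2 and 3, and in the Dmrt1 het Rar mutants 0.127. The first lies between the values set for and against this explanation. Rar mutants 2 and 3 have high title numbers and the other 3 Rar-deleted ovaries low ones, so the difference among Rar-deleted ovaries coincides with the batch. The labels give no cycle stage, so cycle stage and an effect of receptor loss that varies between animals or batches cannot be told apart here.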

How the results depend on the processing

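Chosen only after the data were seen were the title-number batch term, with or without Rar mutant 3, and the DESeq2 fit with shrunken fold changes. For all Rar-deleted ovaries against control, other size factors, filters, edgeR without robust estimation, limma-voom, limma-trend, the equal-weight mean and a fold threshold gave 17 to 25 genes, near the 21 reported. DESeq2 gave 168, a surrogate variable 49, an adjusted p under 0.1 50, the batch term 40, the batch term without Rar mutant 3 2, the 6 libraries of higher title number 142, and leaving out a library 5 to 52. For Rar mutants (2 reported) these were 374, 51, 64, 85, 3 and 142, with 187 for DESeq2 with shrunken fold changes, 1 in a fit of the 2 groups alone and 1 to 384 with a library left out. For Dmrt1 het Rar mutants (4 reported) DESeq2 gave 346, a surrogate variable 8, an adjusted p under 0.1 7, the batch term 1 and leaving out a library 0 to 364. Between the kinds of Rar-deleted ovary (0 reported), DESeq2 gave 682, a surrogate variable 1 and leaving out a library 0 to 335. A replicate block, which assumes that equal replicate numbers belong together, gave 0 for all Rar-deleted ovaries, 2 for Rar mutants and 0 for Dmrt1 het Rar mutants, and with that block Rara in Rar mutants was -0.0120 against 0.05. Correlations of the deviations of libraries with equal numbers ran from -0.0953 to 0.442, which neither shows nor excludes that the numbers pair the samples. Targeted genes called were 0, and 1 with DESeq2. Gene lists called were 7, with 0 at an estimated correlation and 3 by fry, and 5 to 9 with a library left out.

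Some named values changed direction. In Rar mutants, leaving out a library gave ranges of -0.0718 to 0.21 for Rara, -1.03 to 3.42 for Ptx3, -0.65 to 3.84 for Edn2, -0.45 to 3.31 for Egr3 and -0.26 to 3.34 for Egr2. The batch term without Rar mutant 3 gave -1.06 for Ptx3, -0.78 for Egr3 and -0.29 for Egr2 there, and -0.00846 for Pgr in all Rar-deleted ovaries. Between the kinds of Rar-deleted ovary the ranges were -0.0212 to 0.26 for Rara, -0.31 to 0.0104 for Rarb and -5.07 to 0.19 for Pgr, and Rarb was 0.0546 with a surrogate variable and 0.0399 with the batch term. Adjusted p for the oocyte list ran from 3.48e-12 to 0.752 and for the immediate early list from 1.05e-05 to 0.377 in Rar mutants with a library left out. The oocyte list in Dmrt1 het Rar mutants turned, with 0.973 with a surrogate variable and 0.00907 with the batch term. For named genes of the pooled comparison, 884 values kept direction and side of the threshold, 145 fell short of it and 27 passed it only under the alternative; for its lists 91 kept both and 28 fell short. With a library left out counts both fell and rose, and the cause was not tested, nor was that of the other shifts. The highest such count for Dmrt1 het Rar mutants against control came without control 1. Between the kinds of Rar-deleted ovary it came without Rar mutant 1. Each of these comparisons then coincided in full with the title-number batch. Where 1 Dmrt1 het library remained, it was assumed to vary like the other groups. Depth limits Dmrt1 and Cyp26a1, which had at most 5 and 20 counts in a library.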

Other observations

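Chosen only after their results were seen were the tests of epithelial junction genes, of clock genes and of shared controls; the regroupings of samples were set earlier, though the batch term used in part of them was added later.

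The 49 genes lower in the authors' table, such as Gpr55, Sectm1b, St14 and Epcam, were also low in the Dmrt1 het Rar mutants, which played no part in choosing them. Their median log2 difference from control in those 2 libraries was -1.43, and 47 of 49 (95.9%) were below control. Since the same 5 controls enter both comparisons, a bias toward the same side is built in. In 20 simulations with no effect in these libraries the median was -0.183 (-0.294 to -0.0791), with 68.3% below control. These simulations leave out the title-number batch: both Dmrt1 het libraries have low numbers, as among controls only control 1 has. For the 49 genes control 1 was at -0.40 against 0.03 to 0.20 in the other controls. Rar mutant 1, also of low number, was at -1.53, beside -1.72 and -1.64 in Rar mutants 2 and 3, of high number. Part of the -1.43 may go with the batch, which was not tested. For the 136 higher genes the observed median was 0.299 (95 of 136 above control), beside a simulated 0.150 (0.00906 to 0.234).

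A list of genes of epithelial junctions and epithelial identity was written after low values of St14, Ocln, Epcam and Cdh1 had been seen. Of its 35 genes, 30 were tested and 3 were called with the batch as a term. Of the other 27, 24 had negative fold changes with the batch as a term. Those with low values in that fit include Epcam (-2.23), the desmosome gene Pkp3 (-1.56), the E-cadherin gene Cdh1 (-1.29), the tight junction gene Cgn (-0.77) and the polarity gene Crb3 (-0.74). Esrp2 (0.75), Pkp2 (0.43) and Cldn1 (0.43) had positive values. A lower expression of such genes as a group in Rar-deleted ovaries is a hypothesis from these data: the median of the 27 uncalled genes was -0.314, below all 10000 random lists matched for expression, with a fry p of 0.00542 and a camera p of 0.0269 with an estimated correlation. Without Epcam and Cdh1, 22 of 25 were negative, with a median of -0.274, a fry p of 0.0113 and a camera p of 0.0461. Having been proposed from these libraries, the hypothesis cannot be settled by them, and single uncalled genes are not shown to differ. The surface epithelium list had a median of -0.35 in the same fit, and whole-ovary counts do not give the number of epithelial cells.

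Dbp, a clock output gene, had a log2 fold change of -1.39 (SE 0.40) in all Rar-deleted ovaries against control. Nr1d1, a clock repressor, had -1.02 (SE 0.36). Arntl (0.77, SE 0.31) and Nfil3 (1.48, SE 0.51), of opposite phase, had positive values. In that comparison edgeR called none of them. The authors' table of Rar mutants against controls, with shrunken log2 fold changes, holds Dbp (-1.22), Nr1d1 (-1.19) and Nfil3 (1.33) but not Arntl. A different time of day at dissection may underlie these values. The mean of output genes was lower by -0.371 and that of opposite-phase genes higher by 0.544, so that their difference was -0.914 (two-sided exact permutation p = 0.103 over 252 arrangements of 5 against 5 libraries). By library, output minus opposite-phase means were -0.85, -1.64 and -1.13 in Rar mutants 1, 2 and 3 and from -0.32 to 0.99 in controls, but -0.24 and 0.81 in the Dmrt1 het Rar mutants, within the range of controls. The labels give no time of dissection, so this cannot be told apart from other differences between the groups.

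Regroupings of the libraries were fitted in the same way. For all Rar-deleted ovaries against control (21 genes), 5 of 100 drawn from the 126 splits into 5 and 5, the real one included, gave as many genes, and the highest other gave 4574, so chance cannot be excluded by this count. The 4 larger splits each put all 4 libraries of low title number on 1 side, which points to that structure of the samples, though another such split, with control 4 beside them, gave 0. A further set of 60 splits kept group sizes within each batch, with the batch as a term. Of these 1, the real one, gave as many as its 40 genes, and the highest other gave 35. Chance is less likely there but not excluded. The batch term was added after the data were seen, and that fit called 2 genes without Rar mutant 3. For Rar mutants against control (2 genes), 7 of 56 splits gave as many, the highest other 489 for control 1, control 2 and Rar mutant 1 as a group, so chance cannot be excluded by the count alone.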
